A study of Mus musculus with 6 samples.

How the data were processed

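Gene expression was measured in purified intestinal epithelial cells of adult mice on Illumina bead arrays, per the labels. M2rtTA mice carry the reverse tetracycline transactivator, a protein that switches on tetracycline-responsive genes when doxycycline is present. The miR-26a transgenic mice carry in addition an allele named eGFP.miR-26a. All 6 mice received 2 mg/ml doxycycline with 10 mg/ml sucrose for 10 days before the cells were purified. Total RNA was taken up with a miRNeasy kit with DNase digestion and turned into biotinylated cRNA with the MessageAmp kit, per the labels' protocols. BeadStudio is the software named, per the submitters' processing notes. Its version and settings are not given in the sources used here.

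The values used are the authors' deposited array intensity values, 1 per probe and array, on a linear scale. The sorted values of the 6 arrays differed by at most 0.3 at any rank, which is the mark of quantile normalization between arrays. The lowest intensity was 97.1 on each array, and no background had been subtracted. The median was 122.8 and the highest value 35274.9 on each array. Quantile normalization gives each array the same distribution, so a change in the total amount of mRNA per cell cannot be seen. A further table holds 12 columns of signals and detection p-values whose names match no sample label. These columns were not used here in any step. The number of arrays, 3 per group, limits the precision.

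The test design, all but 2 of the alternative settings, the gene lists and the rule for named genes were set before the data were examined. The design called for background correction with limma's neqc and a filter on detection p-values, with log2(intensity + 16) as the fallback. The values used carry no control probes and no detection p-values, so the fallback was taken. In place of the detection filter, a background level was read from the arrays. The mode of the intensities was 113 and the SD of their mirrored lower tail 4.39. A probe was tested if it lay more than 3 such SDs above the mode, at 126.4, on at least 3 of the 6 arrays. This filter was set after the files were seen and before any comparison was run. It passed 20308 of 45281 probes. Between 44.25% and 44.27% of the probes on an array were above the threshold.

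Each tested probe was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate. Differences are transgenic minus control on the log2(intensity + 16) scale. This scale and the background left in the intensities shrink the differences of dim probes. P-values were adjusted over the probes tested by Benjamini and Hochberg's method. "Called" means an adjusted p under 0.05. The samples are separate mice per the series design, and the p-values measure the spread between these 6 preparations. Means and SDs of intensity are over 3 arrays.

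The platform annotation gave 1 gene symbol to 34885 probes, several to 18 and none to 10378. Symbols were looked up by gene identifier in a RefSeq table of the assembly GRCm38.p6, which held 34807 of the probes with 1 symbol. The lookup changed 0 symbols, and the other 78 kept the annotated name. No coordinates are given, since the annotation of the array names no build. A gene stands for its brightest tested probe, and the tested probes stood for 10850 genes. Other tested probes of a gene were compared with it.

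The rule for named genes had several parts. In each direction it took the 12 genes with the largest called differences whose 3 transgenic arrays all lay beyond the 3 control arrays, leaving out clone and predicted names. This left out 3 called genes. It also took up to 4 genes with the smallest p of each gene list, and 9 genes fixed in advance, of which 8 are reported here.

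The 33 gene lists cover intestinal cell types, other cell types, gut segments, the cell cycle, metabolic and stress pathways and published miR-26 targets. They were written from general knowledge and not chosen on these samples. The 32 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares the genes of a list with all other genes. Camera with an estimated correlation and fry were the alternatives. Fry's directional p asks whether the genes of a list move on balance in 1 direction and makes no comparison with other genes. Calls of list members were also adjusted over the list alone.

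The procedure was tested on simulated data with the means and spreads of the 20308 probes for the comparison of transgenic and control arrays. Of 100 probes changed by 0.5 on the log2 scale, 80% were recovered, and of 100 changed by 1, 97%. Unchanged probes made up 4.84% of the calls. A list shifted by -0.30 was called, and 3 lists were called in all. Only 1 of the others shared genes with the shifted list. The probes were drawn independently, so the simulation does not show how correlated genes affect the tests.

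Alternatives were log2 of the deposited values with no pseudocount, normexp background correction with offsets of 50 and 16, no filter, a stricter filter, a replicate block, eBayes with trend and robust settings, array weights, and each array left out in turn. Of these, normexp with offset 16 and the stricter filter were added after the data were seen. A planned test of 3′ UTR sites matching the miR-26a seed was not run, since no 3′ UTR sequence was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.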

Results

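Transcript levels were compared in intestinal epithelial cells from 3 control mice (M2rtTA) and 3 mice that also carried the doxycycline-inducible miR-26a allele, all given doxycycline for 10 days. miR-26a is a microRNA, a short RNA that lowers the levels of mRNAs carrying matching sites. The series concerns the role of miR-26 in intestinal tumour formation, and these arrays compare the epithelium of mice with and without the inducible allele. By genotype, the control mice lacked the whole eGFP.miR-26a allele. An effect of miR-26a thus cannot be told apart from one of eGFP or of the inserted allele. No probe carried the name of miR-26a or of eGFP, so induction of the allele was not measured here. Pairs of control arrays correlated at 0.991 to 0.993 over the tested probes, pairs of transgenic arrays at 0.984 to 0.991 and pairs across the groups at 0.978 to 0.990. These correlations are across probes, which are not independent replicates.

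On the log2(intensity + 16) scale, the iron exporter ferroportin (Slc40a1) rose most in the transgenic epithelium among the called genes named here, by 2.05 ± 0.26 (SE). Aamdc fell most among them, by 1.13 ± 0.06, but was not the largest fall with normexp at offset 16. Avil, Sh2d6, Kctd12 and Alox5ap, markers of the chemosensory tuft cells, fell. The Paneth cell antimicrobial gene Ang4 and the alpha-defensin Defa39 fell as well. The bright Paneth markers Lyz1, Defa20 and Defa3 were not called, and lay at the top of the intensity range. Among published targets of miR-26, the acyl-CoA synthetase gene Acsl3 fell, and Ezh2, Rb1 and Cdk6 did not pass the test. The limma test called 227 of 20308 probes at an adjusted p under 0.05, of which 85 were higher and 142 lower in transgenic mice.

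The 227 called probes were 1.12% of those tested, and 3289 probes had an unadjusted p under 0.05, of which 1603 were higher and 1686 lower. The smallest adjusted p was 0.00992. The median size of the called differences was 0.51 on the log2 scale, and 11 called probes differed by 1 or more, 6 higher and 5 lower. In all 227 the transgenic arrays did not overlap the control arrays. The same held for 4350 of the tested probes, or 21.4%, where 10% would be found by chance. By their brightest probe, 151 genes were called, 60 higher and 91 lower, and 29 called probes had no gene name here. These counts rested on every control array. Without control 1, control 2 or control 3, 0 probes passed the adjusted limma threshold, and 2575, 2431 and 2932 had an unadjusted p under 0.05. Without transgenic 1, transgenic 2 or transgenic 3, 4, 439 and 10 probes were called.

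Slc40a1 rose from an intensity of 445 ± 28.4 (SD, n = 3) in control mice to 2001 ± 854 (n = 3) in transgenic mice, with an adjusted p of 0.0339 from limma. The retinol dehydrogenase gene Rdh7 rose by 1.21, and its other probe stood at 1.41 with an adjusted p of 0.0636. Plagl2, a zinc finger transcription factor, rose from 2780 ± 177 to 5724 ± 1065, or by 1.02 on the log2 scale. Agmat rose by 0.94, Ccdc3 by 0.92 and Mmd by 0.88. Mfge8, a secreted protein that bridges dying cells and phagocytes, rose by 0.79, and its other probe was also called at 0.77. The small heat shock protein gene Hspb6 rose by 0.77 with little spread, from 485 ± 14.9 to 841 ± 16.5 (adjusted p = 0.0105). Scgb2b7 rose by 0.78, Papln by 0.73 and the neonatal Fc receptor gene Fcgrt by 0.72. The other Fcgrt probe stood at 0.54 with an adjusted p of 0.0938. Hif3a, a hypoxia-inducible factor subunit, rose by 1.12 on its brightest probe, from 147 ± 3.99 to 342 ± 72.5. Its other probe, at 147 in control mice, stood at -0.09 and was not called. The death receptor gene Fas rose by 0.71 on its brightest probe, from 216 ± 16.9 to 365 ± 53.7, with an adjusted p of 0.0499. The other Fas probe stood at 0.26 and was not called.

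Aamdc fell from 1611 ± 67.9 to 727 ± 36.4 (SD, n = 3 each; adjusted p = 0.00992 from limma). Atp6v0e, a subunit of the vacuolar proton pump, fell from 1978 ± 204 to 910 ± 69.1, a log2 difference of -1.10. Tmed10, a carrier of secretory cargo, fell by 0.95 on the log2 scale, and its other probe was called at -1.17. Gmds, an enzyme of GDP-fucose synthesis, fell from 6356 ± 900 to 3316 ± 502, a log2 difference of -0.94. Cd8b1, the beta chain of the CD8 co-receptor of T cells, fell from 3793 ± 225 to 2013 ± 74.3, a log2 difference of -0.91. A dim second probe of Cd8b1, at 167 in control mice, stood at -0.11 and was not called. Lrmp fell by 0.91 on the log2 scale and its other probe was called at -0.38. Pdcd10 stood at -0.86 and was called. The beta-galactosidase gene Glb1 was called at -0.83, while its dim other probes stood at -0.02 and 0.22 and were not called.

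**Figure D1:**
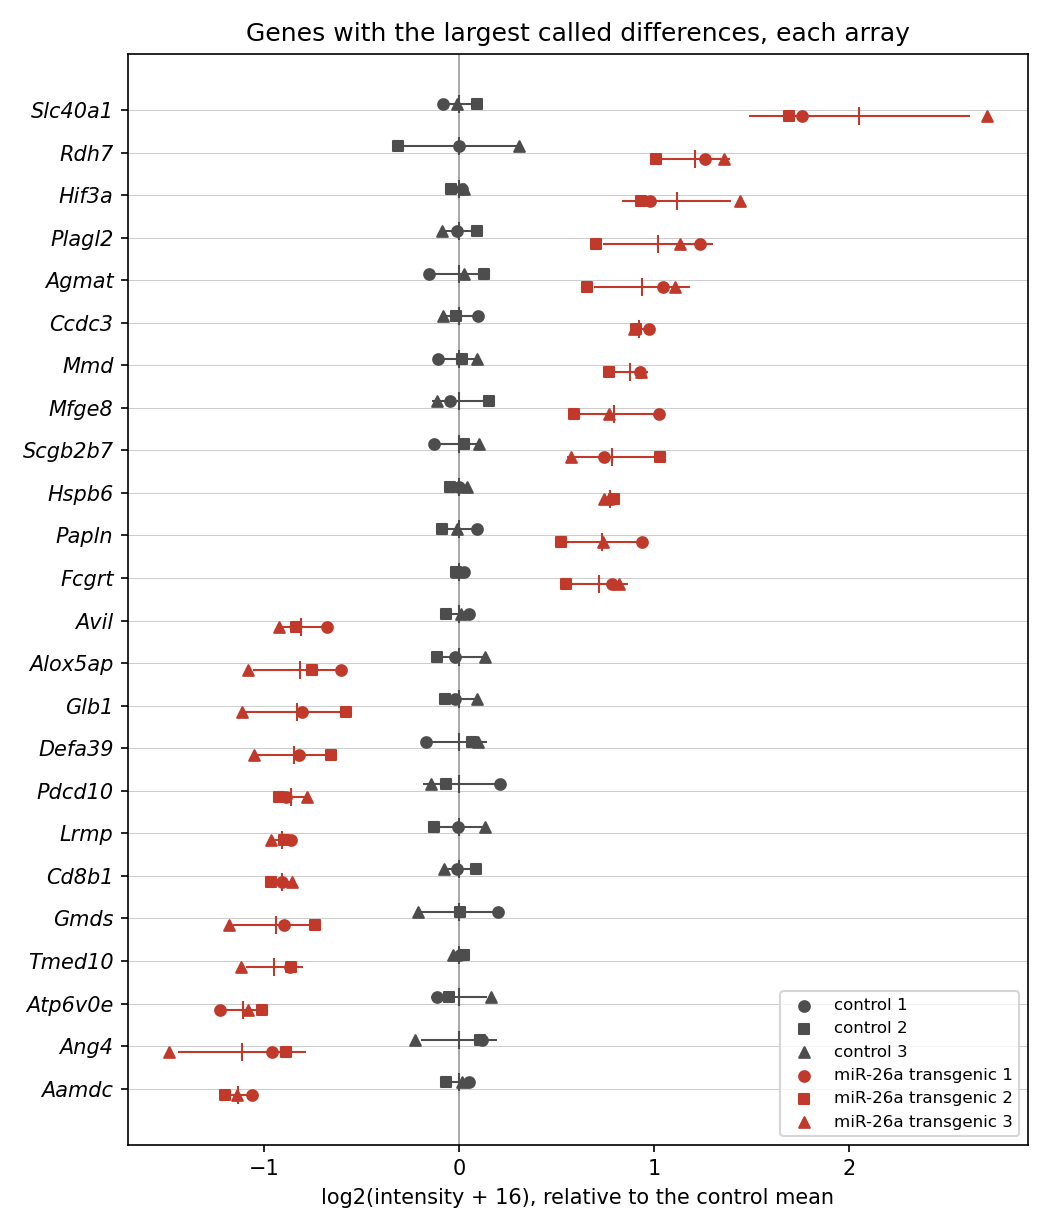
Each array's log2(intensity + 16) relative to the control mean (horizontal axis) for the 24 named genes with the largest called differences (vertical axis). Grey points are the 3 control arrays and red points the 3 transgenic arrays, drawn a little apart, with ticks at the group mean and bars of 1 SD. No transgenic point lies among the control points of its gene, and Slc40a1 (2.05) and Aamdc (-1.13) have the largest mean differences in each direction.

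Tuft cell markers were lower as a list by camera and by fry. Of 13 tested markers, 4 fell and 9 were not called, 8 were lower adjusted over the list alone, and all 13 estimates lay below 0 with a median of -0.33. Avil, an actin-binding protein, fell from 336 ± 14.7 to 185 ± 17.4 (n = 3 each; adjusted p = 0.0168 from limma). Sh2d6 was called at -0.65 and Kctd12 at -0.66. Alox5ap, which activates leukotriene synthesis, fell by 0.81 on the log2 scale, and its other probe was called at -0.81. Dclk1, a widely used tuft cell marker that was chosen after its values were seen, stood at -0.41 (adjusted p = 0.0714). Camera called the tuft list (adjusted p = 3.56e-08), and so did fry (adjusted p = 0.0391). Its call was lost with an estimated correlation (adjusted p = 0.473 with an estimated correlation). The median of immune cell markers was 0.01 over 14 tested genes (camera adjusted p = 0.479), of which Cd8b1 alone was called.

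Published miR-26 targets were lower as a list by camera. Of 26 tested targets, 1 fell and 25 were not called, 3 were lower adjusted over the list alone, and 21 of the 26 estimates were below 0 with a median of -0.14. Acsl3 fell from 402 ± 43.9 to 242 ± 17.0 (n = 3 each), a log2 difference of -0.69 with an adjusted p of 0.0361 from limma. Ctdsp2, a phosphatase gene of the family that hosts the miR-26 genes, stood at -0.65 ± 0.13 (adjusted p = 0.0798), and the cyclin gene Ccnd2 at -0.59 (adjusted p = 0.106). The related Ctdsp1 stood at -0.18 and Ctdspl at -0.16. Ezh2, the methyltransferase of the polycomb repressive complex, had an intensity of 824 ± 74.0 in control and 649 ± 81.3 in transgenic mice, a log2 difference of -0.34 ± 0.11 (adjusted p = 0.189). The retinoblastoma gene Rb1 stood at -0.16 (adjusted p = 0.443), Cdk6 at -0.13 (adjusted p = 0.369), Ccne1 at -0.25 (adjusted p = 0.171) and Ccne2 at -0.21 (adjusted p = 0.316). Camera called the list (adjusted p = 0.000810). The call was lost with an estimated correlation (adjusted p = 0.473 with an estimated correlation), and fry gave an adjusted p of 0.0603.

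Cell cycle and stem cell lists were lower by camera. The list of G2/M and mitosis genes had 21 tested members, of which 1 fell, 5 were lower adjusted over the list alone and 18 had estimates below 0, with a median of -0.23 (camera adjusted p = 6.56e-05 and adjusted p = 0.767 with an estimated correlation). Birc5, the mitotic survival factor survivin, fell from 2121 ± 40.3 to 1509 ± 83.9 (n = 3 each; adjusted p = 0.0248 from limma). Of 34 G1/S and DNA replication genes 0 were called, 9 were lower and 2 higher adjusted over the list alone, and the median was -0.13 (camera adjusted p = 0.00199 and adjusted p = 0.767 with an estimated correlation). Cdk2 stood at -0.48 (adjusted p = 0.0572) and the transcription factor gene E2f1 at 0.31 (adjusted p = 0.105). Of 17 intestinal stem cell markers 0 were called, and the median was -0.13 (camera adjusted p = 0.0137 and adjusted p = 0.767 with an estimated correlation). The stem cell list was not called without control 2 (adjusted p = 0.132) or transgenic 2 (adjusted p = 0.0932). The calls of these lists were thus lost with an estimated correlation. Array medians of the groups overlapped on each of these lists. For G2/M they were -0.086, -0.304 and -0.288 in transgenic mice and 0.017, 0.081 and -0.104 in control mice. For G1/S they were -0.170, -0.0269 and -0.177 against -0.0275, 0.0568 and -0.0324. For stem cell markers they were -0.074, -0.243 and -0.093 against -0.011, 0.084 and -0.098.

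Secretory lineage lists were lower by camera too. Of 11 tested Paneth cell markers, 1 fell, 3 were lower adjusted over the list alone and 9 had estimates below 0, with a median of -0.54 (camera adjusted p = 0.00199 and adjusted p = 0.767 with an estimated correlation). Ang4 fell from 15689 ± 2042 to 7341 ± 1556 (n = 3 each; adjusted p = 0.0494 from limma). The secreted phospholipase gene Pla2g2a stood at -0.99 (adjusted p = 0.0685). The brightest listed markers moved little, with Lyz1 at 0.08, Defa20 at -0.05 and Defa3 at -0.08, none of them called. They fall outside the rule for named genes. Their group means, from 26818 to 34811, lay at the top of the intensity range (highest value 35274.9). Defa39, which is not in the list, fell from 14278 ± 1398 to 7975 ± 1086. Ang4 and Defa39 belong to families of near-identical genes, so their probes may also bind transcripts of related genes, and the gene behind each signal is uncertain. Of 15 goblet cell markers 0 were called, 2 were lower adjusted over the list alone, and the median was -0.08 (camera adjusted p = 0.0397 and adjusted p = 0.767 with an estimated correlation). The goblet list was not called without control 1 (adjusted p = 0.144), transgenic 1 (0.123) or transgenic 3 (0.125). Its array medians were -0.17, -0.05 and -0.15 in transgenic mice and 0.06, 0.04 and -0.09 in control mice. The Paneth and goblet calls were thus lost with an estimated correlation. Of 20 enteroendocrine markers 0 were called, 2 were higher and 4 lower adjusted over the list alone, and the median was -0.14 (camera adjusted p = 0.0914). The markers higher over the list alone were the transcription factor genes Neurog3, at 0.36 (adjusted p = 0.0708 over all probes), and Pax4, at 0.28 (adjusted p = 0.0573).

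The list of duodenum and proximal small intestine markers was higher by camera at the preset correlation. Of 13 tested markers, 1 rose (Slc40a1, also the only one higher adjusted over the list alone), and all 13 estimates were above 0 with a median of 0.64 (camera adjusted p = 0.000812 and adjusted p = 0.767 with an estimated correlation). The lactase gene Lct stood at 768 ± 426 in control and 1714 ± 757 in transgenic mice (n = 3 each; adjusted p = 0.287 from limma). The arrays of each group differed widely on this list: relative to the control mean of each gene, the median was 0.81, 0.19 and 1.33 on the transgenic arrays and -0.23, -0.18 and 0.30 on the control arrays. Of 12 ileum and distal small intestine markers 0 were called, and the median was 0.07 (camera adjusted p = 0.385). Estimates were above 0 for 7 and below 0 for 5. The array medians were -0.22, 0.48 and -0.13 in transgenic mice and 0.18, -0.20 and -0.03 in control mice. The ileal marker Fabp6 stood at 4733, 12725 and 5526 on transgenic 1, 2 and 3, against 10959 to 13495 on the control arrays. Its log2 difference was -0.78 (adjusted p = 0.345 from limma).

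Interferon response and xenobiotic metabolism genes were higher as lists by camera and cholesterol synthesis genes lower, with 0 members called in each. The interferon list had a median of 0.41 over 21 genes (camera adjusted p = 0.00199 and adjusted p = 0.815 with an estimated correlation). Its array medians were 0.08, 0.01 and 0.89 in transgenic mice and 0.09, -0.14 and 0.08 in control mice. Igtp, an interferon-induced GTPase, stood at 1.57 (adjusted p = 0.211). Without transgenic 3 the median was 0.04 and the list was not called (adjusted p = 0.33). The xenobiotic list had a median of 0.38 over 18 genes (camera adjusted p = 0.00452 and adjusted p = 0.767 with an estimated correlation), with 3 higher and 1 lower adjusted over the list alone and was not called without transgenic 3 (adjusted p = 0.125). Its array medians were 0.44, -0.0035 and 0.71 in transgenic mice and 0.05, -0.18 and 0.18 in control mice. The cholesterol list had a median of -0.20 over 17 genes (camera adjusted p = 0.00707 and adjusted p = 0.767 with an estimated correlation). It was not called without control 1 (adjusted p = 0.0668) or transgenic 1 (adjusted p = 0.103). Its array medians were -0.33, 0.0039 and -0.33 in transgenic mice and 0.08, -0.14 and 0.05 in control mice. All 3 calls were thus lost with an estimated correlation.

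In all, camera called 11 of 32 lists, 3 higher and 8 lower. At the same preset correlation, the 9 other splits of the 6 arrays into 3 and 3 called from 6 to 14 lists. The number of lists called thus does not set the real grouping apart. With an estimated correlation 0 lists were called and 2 had an unadjusted p under 0.05, and fry called 1. The other 21 lists had camera adjusted p-values from 0.0554 to 0.882. Among them, 11 mesenchymal, muscle and vessel markers had a median of 0.27 (adjusted p = 0.0922), with an array median of 0.53 on transgenic 2 against 0.0019 and 0.17 on the other transgenic arrays.

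**Figure D2:**
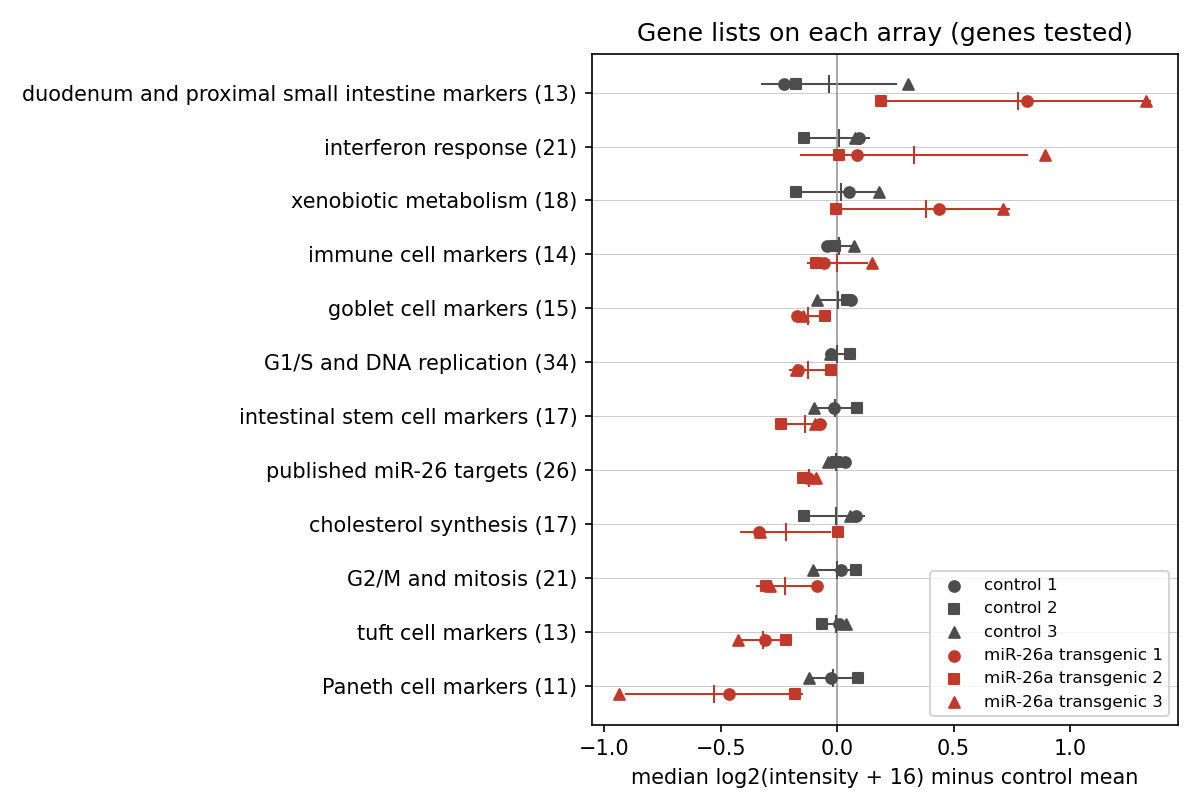
Median over genes of log2(intensity + 16) relative to each gene's control mean (horizontal axis), per array, for the 11 lists called by camera and for immune cell markers (vertical axis, with the genes tested). Grey points are the 3 control arrays and red points the 3 transgenic arrays, with ticks at the group mean and bars of 1 SD. Tuft cell markers lie at -0.31, -0.22 and -0.43 on the transgenic arrays, while the interferon list is high on transgenic 3 (0.89).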

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

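Normexp with offset 16 and the stricter filter were chosen after the data were seen. Array weights called 389 probes (163 higher, 226 lower) and eBayes with trend and robust settings called 347 (131 higher, 216 lower), sharing 227 and 184 with the 227 reported; the cause was not tested. The other scalings and filters called 199 to 280. With each array left out in turn the count ran from 0 to 439 (higher from 0 to 194, lower from 0 to 245), with fewer arrays to estimate the spread. Same-numbered arrays of the groups correlated in their deviations at 0.09, -0.08 and 0.15, and unlike-numbered arrays at -0.34 to 0.28. These values do not show that the numbers pair the mice. With 3 arrays per group they cannot exclude it either. With a replicate block, limma called 0 probes (0 higher, 0 lower) and 3161 had an unadjusted p under 0.05, with fewer degrees of freedom left. Camera called 0 lists with an estimated correlation, fry called 1, and all other settings called 8 to 16. No named gene or called list changed direction in any setting. All 29 called named genes were kept with no pseudocount, with normexp at offset 50, with trend and robust settings and with array weights, 28 with normexp at offset 16, 28 of 28 tested with the stricter filter, and 17 with no filter. With an array left out, 0, 0 and 0 stayed called without control 1, 2 or 3, and 1, 28 and 7 without transgenic 1, 2 or 3. Median scaling, a chip block and the filters on detection p-values were not run, since the values used carry none of what these need, nor were the 3′ UTR site tests, since no 3′ UTR sequence was used here. Probes near the background of 113 have compressed differences: the tuft median of -0.33 became -0.59 with normexp at offset 16. Over the 17 alternative settings for lists it ran from -0.59 to -0.13. With normexp at offset 16, Sh2d6 stood at -1.40, Avil at -1.35 and Kctd12 at -1.28, against -1.25 for Aamdc.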

Other observations

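The tests of tuft cell markers against immune cells and against other secretory cells were chosen after the result was seen. The test of neighbouring genes was chosen after the called probes were seen and before its own count was known. The other tests here were chosen before their results were seen, but the checks on what the covariate, immune, secretory and target tests can decide were added afterwards.

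Car4, a membrane-bound carbonic anhydrase in the list of colon markers, had an intensity of 992 ± 116 in control and 330 ± 185 in transgenic mice (SD, n = 3 each), a log2 difference of -1.67 (adjusted p = 0.0864 from limma). Slc9a3, a sodium and proton exchanger of the brush border, stood at 295 ± 96.0 and 747 ± 191, a log2 difference of 1.31 (adjusted p = 0.083). The lipase family gene Pnliprp2 stood at 4348 ± 958 and 1995 ± 473, a log2 difference of -1.12 (adjusted p = 0.0683). Each was called adjusted over its list alone, and none of these lists was called by camera (adjusted p = 0.70 for colon, 0.385 for ileum and 0.134 for pancreatic acinar markers).

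The 4 tested red blood cell genes had a median log2 difference of -1.57, with array medians of -1.49, 1.37 and 0.09 in control mice and -1.47, -1.07 and -2.13 in transgenic mice. The MHC class II list had a median of -0.41 over 8 genes (camera adjusted p = 0.0914), with array medians from -0.64 to 0.62 in control mice. Absorptive enterocyte markers had a median of 0.23 over 26 genes (camera adjusted p = 0.0554). Apoptosis regulators had a median of -0.0020 over 16 genes and p53 target genes of 0.02 over 16, and Fas, which is in both lists, was the member called. The unnamed probes ILMN_2476405 and ILMN_1238547 rose by 1.48 and 1.34 on the log2 scale, and ILMN_2715802 and ILMN_2507810 fell by 1.02 and 0.84 on the log2 scale.

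The first pattern weighed is the set of 227 called probes. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05; 1 split, the real one, called as many probes, and the highest of the others called 0. With the array mean of the proximal list as a covariate, the log2 differences of the called probes kept a median ratio of 0.972 to their former size (quartiles 0.886 and 1.06), and with the mean of the cell cycle lists 0.948 (quartiles 0.801 and 1.09). These ratios decide nothing on gut segment or the share of cycling crypt cells, which stay open: the called probes had a median SD within groups of 0.08, against 0.33 for 363 uncalled probes that differed by as much as the median called probe or more, so a covariate can hardly move them. Strain variants near the inserted alleles would put called genes side by side. By the order used, 17 of 151 called genes had another called gene among the 5 nearest tested genes on either side. The median was 19 in 10000 random draws (95% from 9 to 31). Start positions were sorted as text rather than as numbers, so genes counted as nearest need not be neighbours. The count therefore decides nothing on strain variants, which stay open. An effect of the miR-26a allele also stays open, as a hypothesis.

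The second pattern is the fall of tuft cell markers. Camera at the preset correlation also called this list in some other splits, with adjusted p of 2.73e-05, 0.0119, 0.0199 and 0.0369. The remaining splits did not call it. Its absolute median log2 difference was 0.33 in the real split and at most 0.21 in the others. Alox5ap, Ptpn6 and other listed genes are also found in immune cells. The immune list had a median of 0.0134 (95% bootstrap interval over genes from -0.0157 to 0.0468) against -0.33 for tuft markers. Only 3 of its 14 genes were as bright in control mice as the dimmest called tuft marker. Of these, Cd8b1 fell by 0.91 on the log2 scale, with its dim second probe at -0.11 and not called. The others, Laptm5 and Ccl5, stood at 0.24 and 0.08 and were not called. With so few bright genes, a loss of immune cells stays open. A fall of secretory types alike stays open as well. The tuft median lay -0.24 from that of goblet and enteroendocrine markers pooled, with an interval from -0.57 to 0.05. The intervals in this paragraph resample genes on the same 6 arrays, so they do not measure the spread between mice. The pooled median was -0.09 (from -0.25 to -0.05), while Neurog3 and Pax4 were higher adjusted over their list alone. Paneth markers were not pooled here, and their median of -0.54 lay below that of tuft markers.

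The third pattern is the lower level of published miR-26 targets. Without the members that are also in the cell cycle lists, the 22 remaining targets had a median of -0.12 and a camera p of 0.00159 at the preset correlation (p = 0.0255 with an estimated correlation, and adjusted p = 0.473 for the full list with an estimated correlation). The low p thus did not rest on the shared members alone. Only those members were left out, so a cell cycle source stays open. In 2 of the 9 other splits these targets also had a camera p under 0.05 at the preset correlation. The smallest was 0.00142, below that of the real split. Of the 10 splits, again too few for a share under 0.05, 4 called at least as many lists as the real one, itself included. The real one called 11 and the highest of the others 14. A direct effect of miR-26a on these targets is a hypothesis that was not tested here.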
